A study of Mus musculus with 20 samples.

How the data were processed

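DNA copy number was measured by array comparative genomic hybridisation, in which sample DNA and reference DNA carry different dyes and compete for the same oligonucleotide probes. Per the labels, 20 arrays were hybridised: 19 with DNA of liver tumours (hepatocellular carcinoma, HCC) of mice labelled Tak1-/-, and 1 with DNA of a healthy wildtype liver. Tak1 is the older name of Map3k7, a kinase upstream of NF-kB and JNK signalling. On every array the sample carried Cy5 and a pool of liver DNA of healthy wildtype C57BL/6 mice aged 3 months carried Cy3, so no array has its dyes swapped. Per the labels' protocols, DNA came from Qiagen columns, was heat fragmented and was labelled by an Agilent protocol written for fixed, embedded tissue. The labels do not say whether the livers themselves were fixed.

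Per the file headers, the scans were read with Feature Extraction 10.5.1.1, which subtracted background and scaled the dyes linearly, without an intensity-dependent correction. The log10 ratio of Cy5 over Cy3 that it wrote for each spot, per the file headers, was the starting point here. The processed and raw intensity of each spot in both channels are deposited with it, without a mean spot intensity. The deposited value table holds, as tested on the files, 2 times the Cy5 over Cy3 ratio of each probe, uncentred, with array medians from 1.94 to 2.07. Its log2 values differed from those of the scanner files by at most 7.24e-06. The submitters' processing notes name Partek without a version, and no step made with it is stated. Probe positions are those of the file headers, on mouse build mm8 (NCBI36). The 20 columns of the value table were matched to the 20 scanner files with 0 unmatched.

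Ratios were converted to log2. Spots that Feature Extraction marked as uneven or as outliers, at most 96 of 43020 on an array, were left out. Spots of the same probe were averaged, giving 42404 probes, of which 40666 lie on autosomes and 1569 on X. A further 167 probes carry no position. Each array was centred on the median of its autosomal probes. Median spacing between autosomal probes was 21.5 kb. Probe noise, the scaled median difference between neighbouring probes, was 0.22 to 0.46 on the log2 scale, and 0.26 on the wildtype array. Between 98.1% and 99.9% of spots were well above background in both channels, and 39558 autosomal probes were so on every array. For arrays the number of animals limits the precision. The headers place the arrays on 6 slides scanned on 3 days. The wildtype array shared slide 1 with tumours HCC_354-3, HCC_357-1 and HCC_357-2. Tumours are named by their titles, without the leading word for the organ, and animals by the part before the hyphen.

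Each autosome of each array was cut into pieces of constant level by least squares, with a penalty per break of 3 times the log of the probe number times the noise variance. Before that, probes over 4 noise SDs from a running median of 11 probes were set to 2 noise SDs from it. A piece of at least 5 probes with a mean log2 ratio of at least 0.25 in size was called a gain or a loss. A chromosome counts as changed as a whole where at least 50% of its probes lie in calls of 1 sign. Tested on simulated arrays, a whole-chromosome change of log2 0.3 was found in 10 of 10 arrays at noise 0.25 and at noise 0.45, and 1 of log2 0.2 in 0 of 10. A run of 10 probes at log2 1.0 was found in 10 of 10 arrays at noise 0.25 and in 5 of 10 at noise 0.45.

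Tumours were grouped into 11 animals by the number before the hyphen of their title. The labels do not state outright that this number is the animal. Tumours of the same animal were averaged before the tests of chromosomes, gene lists, calls, age and single probes. Recurrence, pair correlations, models with a block and relations within a scan day used single tumours. The median log2 ratio of each of the 19 autosomes was tested against 0, the reference pool, with an exact two-sided sign-flip permutation test over animals and Benjamini-Hochberg adjustment. On simulated data with no change, 5.05% of 2000 such tests were under 0.05. Recurrence was the number of animals with a call over more than 50% of the probes of each 1 Mb bin. An animal counted where at least 1 of its tumours had the call. The highest count was set against that after 1000 circular shifts of every animal's calls along the genome. Profiles of 1 Mb bins were correlated between tumours, and same-animal pairs were set against other pairs with 100000 permutations of the animal labels, two-sided. Altered share and age were related by Pearson's r and Spearman's rho with two-sided permutation p-values, 2 relations in the family. Single probes were compared between the 11 animal means and the wildtype array with limma 3.58.1, which assumes that the lone wildtype array varies like the animals. On simulated data for that comparison, limma recovered 0% of 50 probes shifted by log2 0.5, 32% at 1, 94% at 2 and 100% at 3, with 6 false calls among 40642 probes.

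The files pair no probe with a gene, and the gene table at hand follows another assembly (GRCm38.p6), so none of its coordinates were used. Genes of the 7 lists fixed before the data were examined were placed by chromosome alone. Each carries the value of its chromosome, so genes of 1 chromosome are not independent measurements. A list's value is the median over its autosomal genes per animal, tested with the exact sign-flip permutation test and adjusted over the 7 lists, with its percentile among 10000 random lists of the same size. A probe result for Map3k7, tests of single genes, gene names inside called regions and loci of lymphocyte receptors were not analysed here for the same reason. Named in the text are, by a rule fixed in advance, up to 6 genes per list on chromosomes called as a whole in at least 2 animals (otherwise the 2 of largest mean), up to 10 probes per direction past the threshold and of 1 sign in every animal, up to 10 regions called in at least 3 animals, and called segments of log2 1 or more in size under 10 Mb. Of the genes that meet this rule, 1 is not reported here.

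X and the Y contig were kept out of calls and tests, because the labels give no sex. Alternatives changed 1 choice at a time: signals corrected by normexp (offset 50, on median signals, since no mean signals were at hand), loess on intensity, the deposited table, centring on the mode, only probes above background on every array, the wildtype array or its smoothed profile over 51 probes subtracted (no GC values were at hand for a GC regression), other call thresholds, probe minimums and penalties, HCC_58A and HCC_58B as 1 animal, each animal left out, and animal or slide as a block. Versions were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.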

Results

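The series compares chromosomal aberrations in the livers of Tak1-/- mice with those of wildtype mice. The 19 tumours came from 11 animals aged 19 to 31 weeks: 4 tumours from animal HCC_273, 3 from animal HCC_272, 2 each from animals HCC_354, HCC_144 and HCC_357, and 1 each from animals HCC_27, HCC_58A, HCC_58B, HCC_258, HCC_285 and HCC_286. Tumours and animals are named by their titles, without the leading word for the organ. The wildtype group holds 1 array. Its title gives an age of 6 weeks and its age label 23 weeks, its disease state is healthy, and its description calls it an HCC sample. The wildtype group has no replicate, so its values carry no spread. All log2 ratios below are against the reference pool, and all values with an error are animal means ± SD over 11 animals unless stated.

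The first question is which chromosomes were gained or lost in the tumours. Chromosome 13 was higher than the pool in 19 of 19 tumours, with a log2 ratio of 0.27 ± 0.11 (n = 11 animals) and 0.02 in the wildtype array. Chromosome 8 followed at 0.19 ± 0.10 and chromosome 4 at 0.13 ± 0.10, each above 0 in 19 of 19 tumours, with −0.01 and 0.00 in the wildtype array. With normexp signals, which shrink the ratios, the 3 means were 0.10, 0.07 and 0.06. Chromosomes 6 and 14 were higher by less, at 0.05 ± 0.06 in 10 of 11 animals and 0.05 ± 0.05 in 10 of 11. Chromosome 18 was lower in 11 of 11 animals, at −0.10 ± 0.05, chromosome 2 in 11 of 11 at −0.08 ± 0.05, and chromosome 1 in 11 of 11 at −0.07 ± 0.07. Chromosomes 3, 11, 15 and 16 were also lower, between −0.06 and −0.07 with SDs from 0.05 to 0.07. Since every array was centred on its autosomal median, these are levels relative to the rest of the genome, and by construction a broad gain lowers the values of the other chromosomes.

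For chromosomes 13, 8, 4, 18, 2 and 1 the exact sign-flip permutation p was 0.000977, the smallest that 11 animals can give, and the adjusted p was 0.00309. The adjusted p was 0.00619 for chromosome 6, 0.00464 for 14 and for 16, 0.00742 for 11, 0.0118 for 3 and 0.0402 for 15. The other 7 autosomes did not pass, with adjusted p from 0.103 for chromosome 7 to 0.822 for chromosome 9. On the slide that held the wildtype array, the 3 tumours of 2 animals had means of 0.18 ± 0.04 (SD over tumours) for chromosome 13, 0.11 ± 0.02 for 8 and 0.08 ± 0.05 for 4. On the other 5 slides the lowest means were 0.17 for chromosome 13, 0.13 for 8 and 0.09 for 4. Chromosome 15 did not pass without any 1 of animals HCC_272, HCC_144, HCC_357, HCC_27, HCC_58A, HCC_58B, HCC_258 and HCC_286, with an adjusted p up to 0.0804. Chromosome 6 did not pass once the wildtype array was subtracted (adjusted p = 0.0599), nor 6 and 14 once its smoothed profile was (0.0742 and 0.068).

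**Figure D1:**
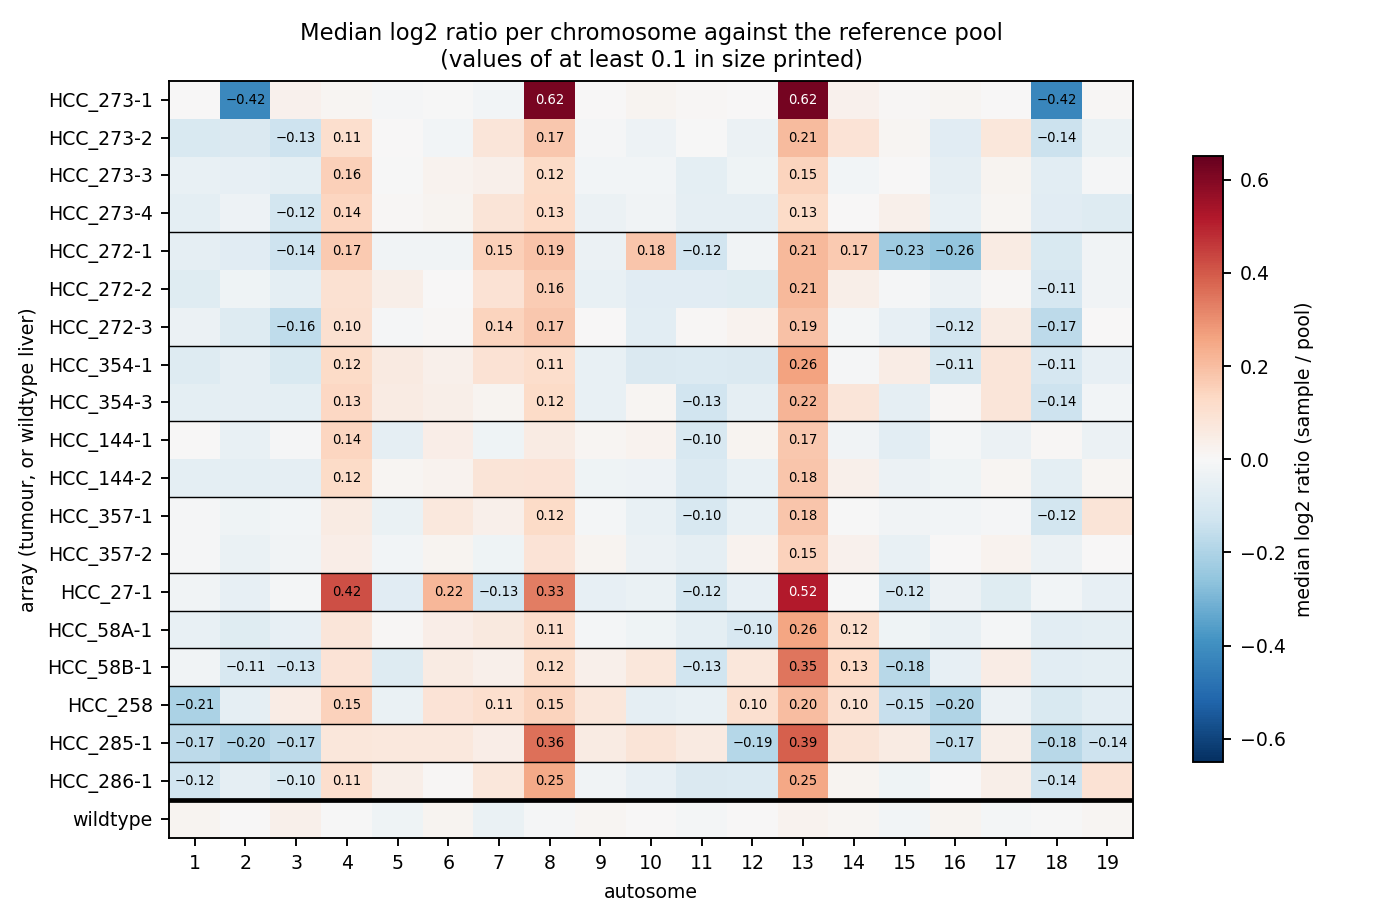
Median log2 ratio (colour, sample over pool) of each autosome (columns) in each of the 19 tumours and the wildtype array (lines of the plot, animals parted by thin rules), with values of at least 0.1 in size printed. Chromosomes 13, 8 and 4 are above 0 in all 19 tumours, and tumour HCC_273-1 has the largest values, 0.62 on chromosomes 8 and 13.

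Whole chromosomes were called as gained or lost in 10 tumours of 9 animals, and in none of the other 9 tumours or the wildtype array. A gain of chromosome 13 was called in 8 tumours of 7 animals: HCC_273-1, HCC_273-2, HCC_354-1, HCC_27-1, HCC_58A-1, HCC_58B-1, HCC_285-1 and HCC_286-1. The same call on chromosome 8 was made in 4 tumours of 4 animals (HCC_273-1, HCC_27-1, HCC_285-1 and HCC_286-1), all of which also had the gain of 13. Chromosome 4 was called in HCC_27-1 and HCC_144-1. The largest values were those of tumour HCC_273-1, where chromosomes 8 and 13 both had a median log2 ratio of 0.62, and chromosomes 2 and 18 were lost at −0.42 each. Its other 15 autosomes lay between −0.02 and 0.03. The only other whole-chromosome loss was that of chromosome 16 in HCC_272-1, at −0.26. The standard error from the spread of probes was at most 0.0138 for these medians. In tumours with no call over more than 10% of the chromosome, chromosome 13 still had a mean of 0.18 ± 0.03 (5 animals, exact permutation adjusted p = 0.099, where 5 animals cannot give a raw p under 0.0625). Chromosome 8 had 0.13 ± 0.03 (7 animals, exact adjusted p = 0.027) and chromosome 4 had 0.10 ± 0.03 (9 animals, exact adjusted p = 0.0106). This restriction was chosen after seeing the data. A whole-chromosome change of log2 0.2 was called in none of the simulated arrays, while the calls on chromosome 13 of HCC_273-2 and on chromosome 4 of HCC_144-1, which cover 64.5% and 52.5% of the probes, go with chromosome medians of 0.21 and 0.14. All 8 tumours of scan day 1 had a whole-chromosome call, against 1 of the 6 of day 2 (HCC_273-2) and 1 of the 5 of day 3 (HCC_354-1).

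**Figure D2:**
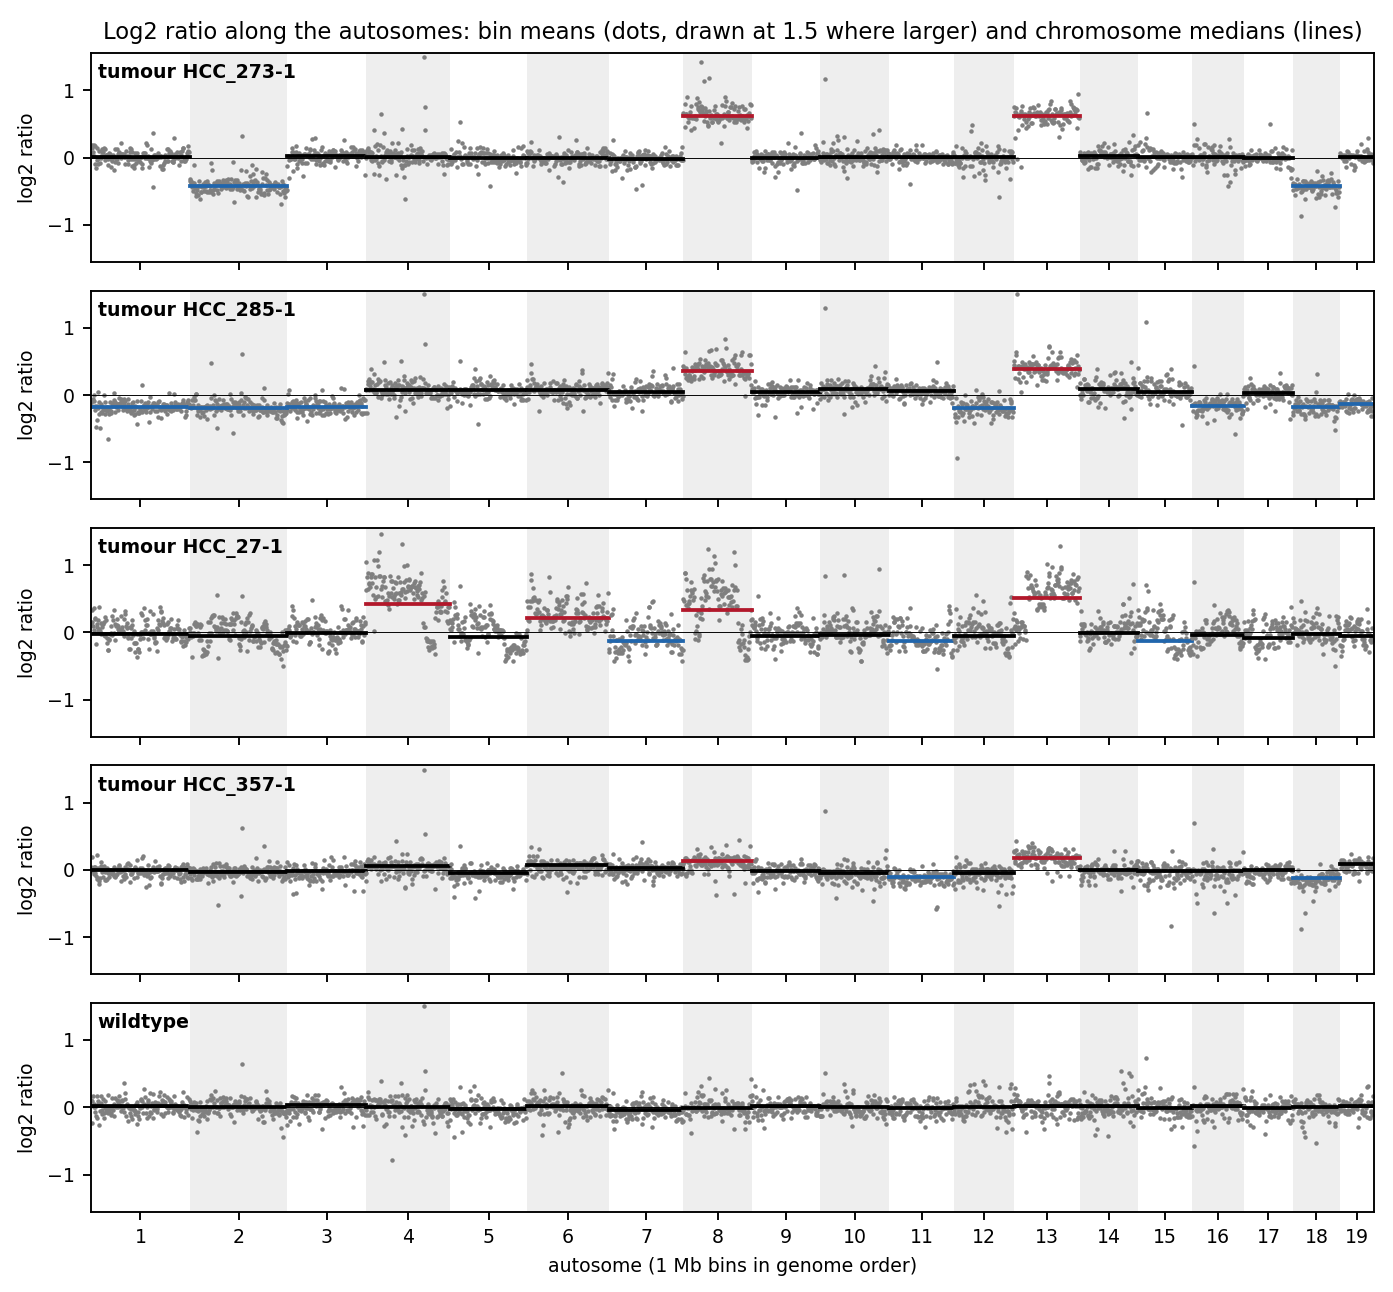
Mean log2 ratio of 1 Mb bins (dots) along the 19 autosomes in 4 tumours and the wildtype array, with chromosome medians as lines (red from 0.1 up, blue from −0.1 down). Chromosomes 8 and 13 stand at 0.62 in tumour HCC_273-1 and at 0.36 and 0.39 in HCC_285-1, and the wildtype medians stay within −0.04 and 0.03.

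The second comparison counts aberrations per array, with the wildtype array called in the same way. The tumours carried 145 calls in all. Calls per tumour, averaged within each animal first, had a mean of 10.4 ± 13.1 and a median of 5 over animals. Among the 145 are 17 short gains on chromosome 4 and 14 on chromosome 14 at places also called in the wildtype array. The wildtype array had 5 calls, 3 of them losses. The number of calls was above that of the wildtype array in 7 of 19 tumours and 4 of 11 animals. The number of losses was above it in 2 of 19 tumours and 2 of 11 animals. The calls covered 7.06% ± 6.55 of autosomal probes in tumours, of which 5.03% ± 4.51 was gained and 2.03% ± 3.05 lost (median 0.091%), against 0.194% altered in the wildtype array. The altered share was 20.4% at a call threshold of 0.15, 1.58% at 0.4 and 1.05% with normexp signals. The altered share was above that of the wildtype array in 14 of 19 tumours and 10 of 11 animals. It ranged from 0.0516% in HCC_354-3 to 22.5% in HCC_27-1, with 21.1% in HCC_273-1, 13.8% in HCC_58B-1, 9.47% in HCC_285-1 and 9.44% in HCC_286-1. The exact permutation p was 0.333 for the altered share and 0.833 for the number of calls, and with 1 wildtype array no p under 0.0833 is possible. Tumours HCC_27-1 and HCC_58B-1 held 41 and 32 calls, and the other 17 tumours at most 7 each. Without them, an alternative chosen after seeing the data, the means were 4.55 calls and 4.59%. On the slide of the wildtype array, the 3 tumours had 0.0516% to 0.214%, of which 1 was above the wildtype array. Of the 5 tumours scanned on its day, 3 were.

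**Figure D3:**
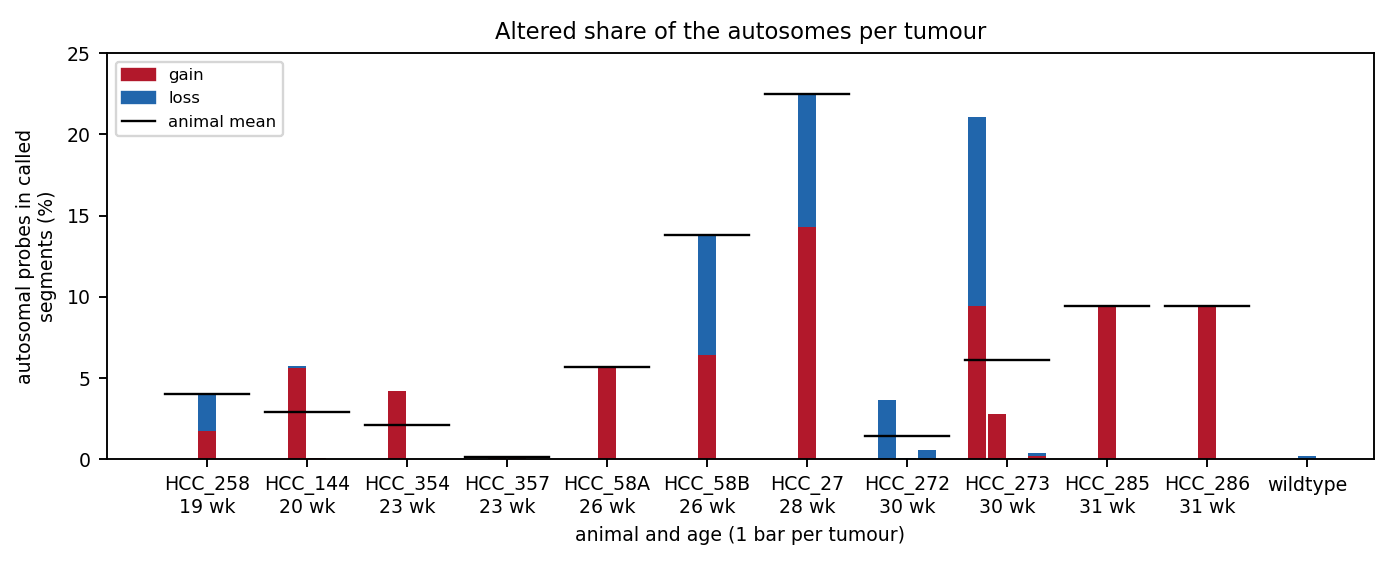
Percent of autosomal probes in called gains (red) and losses (blue), 1 bar per tumour, for 11 animals in order of age and the wildtype array; black lines are animal means. Animals HCC_27, HCC_58B, HCC_285 and HCC_286 have means of 22.5%, 13.8%, 9.47% and 9.44%, and the wildtype array has 0.194%.

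The third comparison asks which regions were changed in several animals. Counted by 1 Mb bins, in which a call must cover more than 50% of the probes, gains of chromosome 13 were shared by 8 of 11 animals from 28016983 to 47972756 and from 58011573 to 67989898 (build mm8), and in 9 tumours in each. The rest of that chromosome was gained in 6 or 7 animals. On chromosome 8 the most shared stretch ran from 50235730 to 70868395, gained in 7 animals, in 7 tumours that were all scanned on day 1 and lay on slides 5 and 6. The 9 tumours with the gain of 13 lay on 4 slides, with 6 of them scanned on day 1. Chromosome 4 from 111041964 to 112283801 was gained in 7 animals. The wildtype array, whose call there starts at 111756513, was gained only in the bin from 112 Mb. Outside the 10 most shared regions, and picked after its value was seen, a gain of chromosome 4 from 3377972 to 40996521 was shared by animals HCC_144, HCC_27 and HCC_58B, whose tumours with it all lay on slide 6. The highest count of 8 was reached in none of 1000 circular shifts, a permutation p of 0.000999, the smallest they can give, where the shifted calls had a 95th percentile of 5. The shifts treat animals as independent and take no account of shared slides and days. With normexp signals the highest count was 2 (permutation p = 0.26), and over all alternatives it ranged from 2 to 11. Losses were shared over such bins by at most 3 animals, HCC_273, HCC_27 and HCC_58B, on chromosome 2 from 24010688 to 33900758 (p = 0.393). The highest count of losses was 7 at a call threshold of 0.15 (p = 0.004), 4 with outlying probes kept (p = 0.022) and 4 with the smoothed wildtype profile subtracted (p = 0.046).

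**Figure D4:**
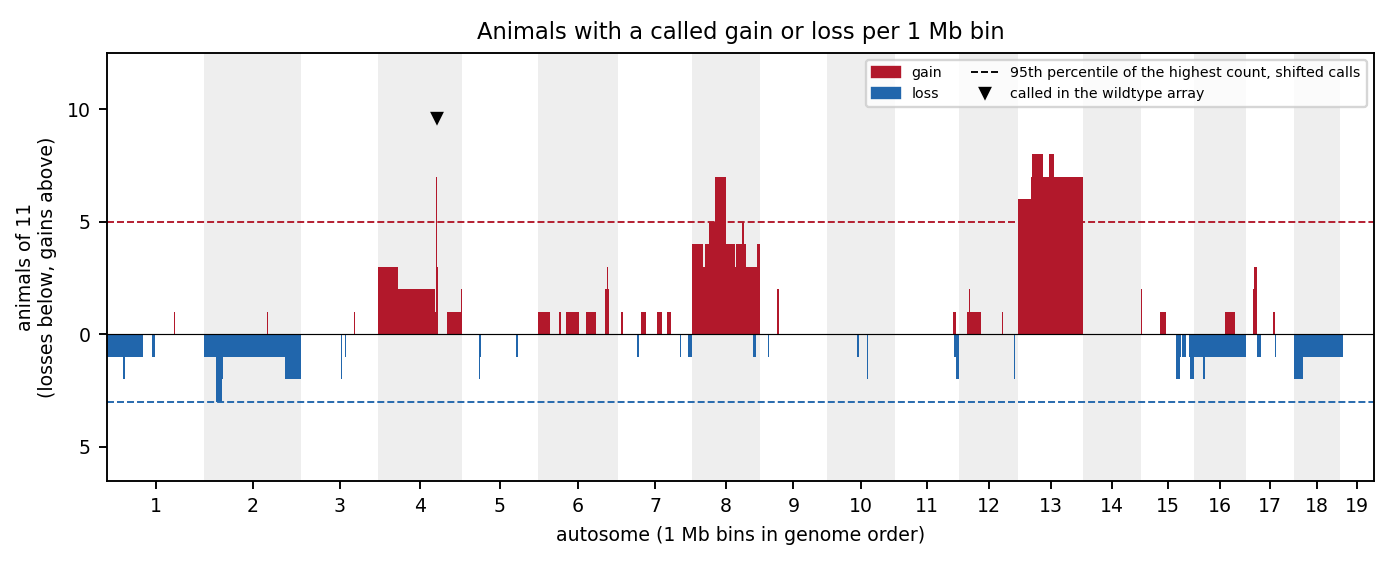
Number of the 11 animals with a called gain (red, upward) or loss (blue, downward) in each 1 Mb bin of the 19 autosomes, with the 95th percentile of the highest count under circular shifts as dashed lines (5 for gains, 3 for losses). Chromosomes 13 and 8 rise above the gain line over long stretches, with at most 8 and 7 animals, and the narrow peak on chromosome 4 is also called in the wildtype array (triangle).

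Short segments of log2 1 or more in size were few apart from regions that also differed between the wildtype array and the pool. The gain at about the same place on chromosome 4 was called in 17 tumours of 10 animals, at 0.85 to 3.12, and in the wildtype array at 2.32 over 11 probes from 111756513 to 112266190. It was not called in HCC_258, and in HCC_144-1 the place lay in a longer gain from 3377972 to 112283742 (0.29). A gain on chromosome 14 from 68212568 to 68418187 was called in 14 tumours of 11 animals at 0.69 to 1.03 and in the wildtype array at 0.78. Outside these, tumour HCC_273-2 had a gain on chromosome 5 from 52528183 to 52848448 (1.12 ± 0.16, standard error from probe noise, 8 probes). Tumour HCC_273-4 had a gain on chromosome 4 from 154968413 to 155028976 (1.26 ± 0.20, 5 probes). A loss on chromosome 9 from 46630511 to 46764155 (5 probes, too short to fill a bin to 50%) was called with the same ends in 4 tumours of 4 animals: HCC_144-2 (−1.02 ± 0.14), HCC_273-1 (−0.86), HCC_27-1 (−0.80) and HCC_285-1 (−0.76, or −0.89 before outlying probes were pulled in). Without a call there, the same probes stood at −0.52 in the wildtype array and between −1.02 and 0.11 in the other 15 tumours.

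The fixed gene lists describe what the changed chromosomes carry, each gene with its chromosome's value. Of the 38 autosomal oncogenes, 8 lay on chromosomes that were higher, 8 on chromosomes that were lower and 22 on neither, adjusted over the list alone, against 8 and 9 over all genes. E2f3, a cell cycle transcription factor, and Tert, the catalytic part of telomerase, are on chromosome 13 (0.27 ± 0.11), and Jun and Mycl, both transcription factors, on chromosome 4 (0.13 ± 0.10). Of 39 tumour suppressors, 13 were on higher and 12 on lower chromosomes, with both counts equal over all genes. Klf6 is on 13, Cyld, Dlc1 and Wwox on 8 (0.19 ± 0.10), and Arid1a and Cdkn2a on 4. Cyld removes ubiquitin chains in NF-kB signalling, and Cdkn2a encodes inhibitors of the cell cycle. Neither list's median passed the test against the pool (0.01 ± 0.04, adjusted p = 0.391, higher in 7 of 11 animals, and −0.01 ± 0.03, adjusted p = 0.462, lower in 8 of 11, exact sign-flip permutation tests). Their percentiles among random lists were 80.5 and 80.2.

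Of 27 autosomal genes of the TAK1, NF-kB and JNK pathway, 6 were on higher and 10 on lower chromosomes, adjusted over the list alone and over all genes alike. Ikbkb, a kinase that releases NF-kB, Map2k7, which activates JNK, and Tradd, an adaptor of the TNF receptor, are on chromosome 8, and Map3k7 itself is on chromosome 4. The value of chromosome 4 says nothing of a deletion inside Map3k7, which was not measured here. Of 19 autosomal cell death genes, 7 were on higher and 7 on lower chromosomes, with both counts equal over all genes. Ripk1 is on 13, Mlkl on 8, and Casp9 and Dffa on 4. List medians were −0.01 ± 0.03 (adjusted p = 0.379, lower in 8 of 11 animals) and 0.01 ± 0.03 (adjusted p = 0.445, higher in 7 of 11) by the exact permutation test. Their percentiles among random lists were 18.9 and 86.2.

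Of 23 autosomal genes of mitosis and DNA damage, 3 were on higher and 9 on lower chromosomes, adjusted over the list alone and over all genes alike. Ccnb1, the mitotic cyclin, is on 13, and Cdc20, which starts anaphase, on 4. The list's median was −0.03 ± 0.03 (exact permutation adjusted p = 0.0661, lower in 10 of 11 animals), at percentile 54.1 among random lists. Of 19 hepatocyte and progenitor genes, 0 were on higher and 7 on lower chromosomes over the list alone, and 9 over all genes. Ttr, a plasma transport protein made by liver, is on chromosome 18 (−0.10 ± 0.05) and Foxa2, a liver transcription factor, on 2 (−0.08 ± 0.05). That list's median was lower, at −0.03 ± 0.03 in 10 of 11 animals, with −0.01 in the wildtype array (exact permutation adjusted p = 0.0444, and 0.0513 with only probes above background on every array). Its percentile among random lists was 15.2. The test is against 0, and the mitosis list, near the middle of its random lists, also had a median of −0.03. The adjusted p therefore does not show that hepatocyte and progenitor genes differ from other genes.

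The list of genes that vary in copy number between mouse strains had the highest median, 0.08 ± 0.05 in 11 of 11 animals against 0.00 in the wildtype array (exact permutation adjusted p = 0.00684, percentile 100 among random lists). Of its 139 genes, 82 were on higher and 29 on lower chromosomes, over the list alone and over all genes alike. They sit in clusters, with 33 on chromosome 4, 25 on 8, 5 on 13 and the rest on other autosomes. The list's median thus reads values of whole chromosomes, these and others, and not 139 separate loci. The random lists drew genes singly, so the percentile takes no account of the clusters. Naip1, Naip2, Naip5 and Naip6, sensors of bacterial proteins, and Nnt, a mitochondrial enzyme that C57BL/6J mice carry with a deletion, are on 13, and the defensin gene Defb1 is on 8.

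Single probes were compared between the 11 animal means and the wildtype array. With limma, 8 of 40664 autosomal probes were higher in tumours and 8 were lower, out of 1454 and 811 at an unadjusted p under 0.05. In 7 of the 8 higher and 6 of the 8 lower probes the wildtype value lay farther from the pool than the tumour mean did. The other 3 had 1 sign in every animal. Probe A_53_P170043 (chromosome 16, 36229265 to 36229321) stood at 3.62 ± 0.50 in tumours and −0.15 in the wildtype array (limma adjusted p = 0.000212, and 0.00127 with slide as a fixed term), and between 2.83 and 4.38 in every animal. Probe A_53_P113682 (chromosome 5, 91563269 to 91563328) stood at −1.53 ± 0.27 and 0.26 (limma adjusted p = 0.00822, and 0.448 with slide as a fixed term). Probe A_53_P141321 (chromosome 16, 59304009 to 59304068) stood at −1.52 ± 0.24 and −0.08 (limma adjusted p = 0.0358, 0.105 with animal as a random block and 0.986 with slide as a fixed term). Against the pool in place of the wildtype array, limma called 2862 probes higher and 1525 lower. Of those higher, 2155 lay on chromosomes 4, 8 and 13, among them 1030 of the 1663 probes of chromosome 13.

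The next comparison asks whether tumours of the same liver share their profile. The mean correlation of 1 Mb bins was 0.337 ± 0.089 (SD, 12 pairs) within animals and 0.33 ± 0.16 (159 pairs) between animals, a difference of 0.007 (two-sided permutation p = 0.888). Animal HCC_273 shows the spread within 1 liver. Tumour HCC_273-1 had 0.62 on chromosome 13, whereas HCC_273-2, HCC_273-3 and HCC_273-4 had 0.21, 0.15 and 0.13, and none of these 3 had its losses of chromosomes 2 and 18. In animal HCC_272, the loss of chromosome 16 in HCC_272-1 (−0.26) stood against −0.04 in HCC_272-2 and −0.12 in HCC_272-3. HCC_273-1 and HCC_272-1 were scanned on day 1, and the other tumours of these 2 animals on day 2. Over pairs on different slides alone the difference was 0.0287 (permutation p = 0.579).

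No relation between the altered share and age passed the test over the 11 animals. Pearson's r was 0.387 (permutation p = 0.244, adjusted 0.244) and Spearman's rho was 0.468 (p = 0.148, adjusted 0.244). Without animals HCC_258 and HCC_144, the 2 farthest from the median age, r was 0.292 (exact permutation p = 0.458). Among the 8 tumours of 8 animals of scan day 1, r was 0.236 (exact permutation p = 0.599), and the other scan days hold 3 animals each, too few for a value.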

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

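X and the Y contig stand outside all comparisons, and some tumours stood apart from the wildtype array on each. No explanation was tested for either. The single probe on a Y contig had a log2 ratio of at least 2.14, and up to 3.76, in 13 tumours of 6 animals (HCC_273, HCC_272, HCC_354, HCC_357, HCC_285 and HCC_286), against 0.15 in the wildtype array. In the same 13 tumours the median of X was −0.79 to −1.13, below the −0.02 of the wildtype array. In the other 6 tumours, of 5 animals, the Y probe stood between −0.89 and 0.32 and X between −0.03 and 0.24. The wildtype array lay within the range of these 6 tumours on both. The labels give no sex for the mice or the pool, so the arrays may differ in it. Among those 6 tumours, HCC_58B-1 had a median X log2 ratio of 0.24, against −0.02 in the wildtype array and at most 0.04 in the other 5. Neither signal was tested against the wildtype group, which holds 1 array. Arrays were tested for standing apart only in groups of 4 to 10, and the groups here hold 19 and 1.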

How the results depend on the processing

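No paired analysis was possible because the compared groups, 19 tumours and 1 wildtype array, share fewer than 2 replicate numbers. Leaving out tumours HCC_27-1 and HCC_58B-1, the 4 tumours of noise over 0.4 (HCC_273-2, HCC_273-4, HCC_272-3 and HCC_144-1) or the tumours called on a chromosome, and testing probes only within the slide or scan day of the wildtype array, were alternatives chosen after seeing the data. The Map3k7 result, single genes and a GC regression were not run. Of 246 alternative values of the main results, 223 kept their direction, side of the threshold or size. For those that did not, the cause was not tested. Values counted as kept can still differ in size. The number of calls counted as kept in 16 of 16 alternatives, while ranging from 3.85 to 22.0 around 10.4. The altered share did so in 15 of 16, and its alternatives ranged from 1.05% to 20.4% around 7.06%. The number of chromosomes that were higher stayed between 4 and 6 and of those lower between 6 and 7. Chromosome 13 ranged from 0.10 to 0.29, 8 from 0.07 to 0.20 and 4 from 0.06 to 0.14, with the lowest values under normexp, and 13 missed the threshold only without the tumours called on it (adjusted p = 0.099, 5 animals). Of 276 alternative values of single chromosomes, 255 kept their call, and most of the 21 lost calls were of chromosome 15, which kept its call in 6 of 23. Chromosome 7 passed in addition with the wildtype array or its smoothed profile subtracted, with centring on the mode, without animal HCC_27, without tumours HCC_27-1 and HCC_58B-1, and without the tumours called on a chromosome, and chromosome 19 was lower in addition without animal HCC_286.

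The altered share was 20.4% at a threshold of 0.15, 1.58% at 0.4 and 1.05% under normexp, and the mean number of calls ranged from 3.85 under normexp to 22.0 at a penalty of 2. The highest number of animals with a shared gain ranged from 2 to 11 over its alternatives. It was 2 under normexp (permutation p = 0.26), and 7 to 8 with an animal left out. For losses it was 4 with the smoothed wildtype profile subtracted (p = 0.046), 7 at a threshold of 0.15 (p = 0.004) and 4 with outlying probes kept (p = 0.022). The same-animal difference was −0.0103 under normexp and −0.00995 under loess, with p from 0.524 to 0.97 over its alternatives. Age gave r from 0.135 to 0.597, with no p under 0.094. Counts of probes that were higher and lower, 8 and 8 with limma, were 0 and 2 under normexp, 5 higher with probes above background on every array, 1 and 2 with animal as a random block, 1 and 3 with slide as a random block, 1 and 1 with slide fixed, 215 and 73 within the slide of the wildtype array, 14 higher within its scan day, and 2862 and 1525 against the pool. At an unadjusted p under 0.05, normexp gave 1364 and 1795. With an animal left out the limma counts were 6 to 10 and 7 to 11. Within the slide of the wildtype array 3 tumours of 2 animals remained, and within its scan day 5 of 3, so counts are not given for these. Within that slide, probes A_53_P170043, A_53_P113682 and A_53_P141321 differed from the wildtype array by 4.079, −1.577 and −1.245. The median of the mitosis list passed under normexp (−0.015, adjusted p = 0.0479), and that of the hepatocyte list did not pass with probes above background (−0.031, adjusted p = 0.0513). Median signals over background of 16.7 to 112 (Cy3) and 38.0 to 82.0 (Cy5) limit the noisiest arrays, where a run of 10 probes at log2 1.0 was missed in 5 of 10 simulated arrays.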

Other observations

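Chromosome medians of 4 tumours, called or not, are given here as values. In tumour HCC_285-1, chromosomes 1, 2, 3, 12, 16, 18 and 19 stood between −0.14 and −0.20, chromosomes 8 and 13 at 0.36 and 0.39, and the other 10 autosomes between 0.04 and 0.08. In tumour HCC_272-1, chromosomes 10 and 14 stood at 0.18 and 0.17 and chromosomes 15 and 16 at −0.23 and −0.26. Tumour HCC_258, from the youngest animal at 19 weeks, had −0.21 on chromosome 1 and −0.20 on 16. Tumour HCC_27-1 had 0.42 on chromosome 4 and 0.22 on 6. These values were picked after they were seen.

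Over the 11 animals, chromosomes 13 and 8 rose together, with r = 0.74 (permutation p = 0.00875, adjusted 0.0263) and rho = 0.727 (p = 0.0145, adjusted 0.0435), 1 of 3 relations computed among 13, 8 and 4. Without animals HCC_27 and HCC_285, the 2 farthest from the median of chromosome 13, r was 0.311 (exact permutation p = 0.41). Leaving them out also narrows the range of chromosome 13, so it cannot show whether the relation rests on those animals. Among the 8 tumours of scan day 1, r was 0.875 (exact permutation p = 0.00451), and the other scan days hold 3 animals each. Chromosomes 13 and 4 gave r = 0.662 (adjusted p = 0.113) with rho = −0.0455 (adjusted p = 0.903), and 8 and 4 gave r = 0.419 (adjusted p = 0.19) with rho = 0.0909 (adjusted p = 0.903).

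For the patterns that follow, both tests of an effect on all arrays, the correlation of the profiles of HCC_27-1 and HCC_58B-1, the test of an outlying wildtype spot and all 3 tests on tumour HCC_273-1 were chosen after the results were seen. Each pattern was found and tested on the same data, so each reading is a hypothesis.

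In the 9 tumours of 5 animals with no call over more than 10% of chromosome 13, 8 or 4, these chromosomes still stood at 0.18 ± 0.03, 0.12 ± 0.03 and 0.12 ± 0.04 (SD over animals). Waves along the genome that ignore chromosome ends are argued against: the spread between chromosome means, 0.0768, was reached in none of 1000 circular shifts (highest 0.0758, share 0.000999, the smallest they can give). An effect of the probes or the pool of 1 size on all arrays is argued against for chromosome 4, because 2 of the 8 other arrays without a call over more than 10% of it, the wildtype array (0.00) and tumour HCC_273-1 (0.01), lay below the lowest of the 9 tumours (0.05) and 3.08 and 2.64 SDs below their mean. For chromosomes 13 and 8 such an effect cannot be told apart from an extra copy in part of the cells: the wildtype array lay below the lowest such tumour on 2 of 2, but it is 1 array. That 100% of the 5 Mb bins of each of the 3 chromosomes lay above 0 in the mean profile does not favour an extra copy, since the chromosomes were picked for lying above 0. With 1 extra copy of 2 the levels would need 26.8%, 18% and 16.7% of cells. An effect that differs in size between arrays was not tested.

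Tumours HCC_27-1 and HCC_58B-1, on the same slide, held 41 and 32 called gains and losses, with both signs on 1 chromosome in 5 and 2 of the 19 autosomes. Changes placed in each tumour without regard to the other are argued against by 1000 circular shifts. Outside chromosomes 4, 8 and 13, 165 bins of 1 Mb were called in HCC_27-1 and 126 in HCC_58B-1. Of these, 41 had 1 sign in both, against a mean of 5.68 under the shifts (share 0.000999, the smallest they can give), and 4 had opposite signs. Separate changes that recur at the same sites would also exceed the shifts, so they stay open. After chromosome medians were removed the profiles correlated at 0.607. A wave profile shared with other arrays cannot be told apart from changes that both tumours acquired: mean correlations with the other 17 tumours were 0.0883 and 0.158, one under and one over the bound of 0.1 set for its absence and both under the 0.2 set for its presence. These means cover values of both signs, from −0.298 to 0.455 and from −0.342 to 0.592, the last with HCC_357-2 on another slide. Values of both signs cancel in a mean, so the 2 bounds cannot decide. The mean over pairs of the 17 was 0.159. Correlations with the wildtype array were 0.283 and 0.472, so part of each profile was not particular to these 2 tumours. Short gains shared with the wildtype array were not removed before these correlations. No GC values were at hand to remove such waves.

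The 3 probes of 1 sign in every animal differ from the wildtype array. A copy change of the surrounding region is argued against, with a mean of at most 0.0924 over the 4 nearest probes. The tumour means of 3.62, −1.53 and −1.52 are against the pool, so a spot on the wildtype array has no part in them. The wildtype array stood at −0.15, 0.26 and −0.08. For the difference from it, an outlying spot there and a variant of the knockout line against the pool cannot be told apart. The smallest animal mean was 1.04 in size against the pool, and 19 of 19 tumours lay on the probe's side of both 0 and the wildtype array, but the probes were chosen for having 1 sign in every animal, and there is 1 wildtype array. The labels give the strain of the pool only, and no probe sequence was compared here.

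A hypothesis on tumour HCC_273-1 concerns its dosage. A gain of 1 copy and a loss of 1 copy of 2 in the same cells is argued against, because the losses stood at −0.421, where the gains of 0.62 predict −1. Gains to 6 and losses to 3 copies of 4 may account for the levels, with predicted values of 0.585 and −0.415 and a largest distance of 0.0361. Gains in all cells with losses in 50.6% of them could give the same levels, and these cannot be told apart by ratios alone. Other mixtures, such as larger copy changes in part of the cells beside unchanged cells, were not computed. The array does not measure ploidy.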
